A study of Pseudomonas putida with 18 samples.

How the data were processed

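The raw counts in the table deposited by the authors were used for every test, and they are read counts per feature per the file headers. Normalized counts, a score made by the authors by a program that is not given in the sources used here, served only to recover their scaling factors, which were tried as another scaling. Of 386 columns, 81 were used (18 raw counts, 18 normalized counts and 45 q-values for pairs of single libraries deposited by the authors), and 297 per-sample or per-pair columns were not. The aligner, the counting program, its use of strand and the genome version are not given in the sources used here, so antisense counts and the counts of identical copies are uncertain. Features were classed as protein-coding, known small RNA, intergenic, antisense or other RNA from the names in the table, and ribosomal RNA regions were recognised from the annotated features antisense to them.

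Counts were fitted in edgeR 4.0.16 with a quasi-likelihood model (glmQLFit, robust) that has 1 mean for each of the 6 groups, TMM scaling and the filterByExpr filter over those groups. Each of 12 comparisons was tested with glmQLFTest, with p-values adjusted by Benjamini and Hochberg over all tested features and a threshold of 0.05. Among them 3 compare the strains within a phase, 6 compare phases within a strain and 3 are differences of the strain effect between phases. CPM values use the TMM-scaled library sizes, and principal components use log2 CPM with a prior count of 2. Where a group had no counts, the ratio to a floor of 3 counts over the group is given as a lower bound, and with 1 to 3 counts the ratio is given with a 95% counting interval.

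Gene lists were fixed as patterns before any count was seen and filled from the gene names and product texts of the table. Of these, 31 with at least 5 tested members were tested with camera on voom values of limma 3.58.1, with a preset correlation of 0.01 between genes and p-values adjusted over the 31 lists. The same test with a correlation estimated from the residuals and the test fry were run beside it. A smaller list, the arginine deiminase pathway, was only counted, and no list was adjusted together with another comparison.

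Wrong matches were corrected after the table was read and before any list was tested. The gene rpoX moved from ribosomal proteins to general stress, greA and greB left translation factors, acoC and pabB left the catabolism list, and lolB left chaperones. Genes named phaB, phaD, phaE, phaH, phaI, phaK, phaL, phaM and phaN, which belong to phenylacetate breakdown in this annotation, left polyhydroxyalkanoate. Choline matches left prophage, PilZ proteins left pili, and transposases were limited to product texts with a transposase or an insertion sequence. The list of amino acid and peptide ABC transport kept transporters of other kinds, such as gabP and sdaC.

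Named genes follow a rule set before any count was seen. It takes called annotated features with a mean of at least 50 raw counts over the libraries compared and, outside the differences between phases, with no overlap between the groups in CPM. In each direction it takes the 12 largest changes in a strain comparison plus 3 unannotated RNAs, 8 in a phase comparison and 5 in a difference between phases, and up to 4 members of each list with the smallest adjusted p. Always named are hfq and its neighbours, crc, rpoS, cbrB and the known small RNAs. The text prints a part of them, mostly those that leaving out 1 library did not change, and gives the change for the rest it prints. Of the genes that the rule takes, 1 is not reported here.

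The code was tested on simulated data of 18 libraries in 6 groups, with 200 of 4804 tested features changed in 1 group, the deletion strain in exponential phase. It recovered 58% of 2-fold and 100% of 4-fold increases, 48% of changes to 0.5 and 98% of changes to 0.25, with 2 false calls among 4604 unchanged features. A smaller real change can thus be missed. The simulated groups were otherwise equal, while far more features changed in the real comparisons, so these rates need not hold there. Camera called a shifted list of simulated genes and did not call an unshifted one. The simulated genes were drawn independently of each other, so this does not test camera on lists whose genes vary together.

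Replicate numbers were checked as a possible pairing. The labels give each number 1 code over the 3 phases of a strain, which does not say that 1 culture was sampled 3 times. Residuals of libraries with the same number correlated at -0.0438 to 0.292 between phases of 1 strain and at -0.0862 to 0.104 between strains at 1 phase. Between exponential and transition phase of the deletion strain all 3 pairs were over 0.1, at 0.155 to 0.292 against -0.194 to 0.0191 for different numbers, and these libraries are taken to be pairs. In the other 8 comparisons of 2 groups at least 1 pair was not over 0.1. Every same-number pair still lay above all others for deletion exponential and stationary phase (0.0293 to 0.131 against at most 0.0242). The same held for deletion transition and stationary (0.0339 to 0.0533 against 0.0160) and wild-type transition and stationary (0.0303 to 0.120 against 0.0103). It also held for the strains in stationary phase (0.0646 to 0.104 against 0.0224), so a weaker pairing is possible in these. The fits reported have no block, and the fits with 1 are given with the sensitivity of the results. Programs were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.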

Results

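Transcripts of wild-type Pseudomonas putida KT2440 and of a strain without hfq were compared in 18 RNA-seq libraries, 3 for each of 2 strains at each of 3 growth phases. Per the labels the bacteria grew in LB medium at 30 °C and were taken in exponential phase at an OD600 of 0.5, at the transition into stationary phase at an OD600 of 2.5, and in stationary phase, for which no OD600 is given. RNA shorter than 500 nucleotides was selected before sequencing, so abundances here are those of short transcripts and fragments. The values are the raw counts of the deposited table for 5906 features, of which 5350 are protein-coding genes, 13 known small RNAs, 246 intergenic small RNAs, 178 antisense RNAs and 50 other predicted RNAs. After the low-count filter 5031 features were tested, 4617 of them protein-coding and 414 RNAs.

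Libraries held 32354925 to 60104433 counts, of which 1393043 to 8771013 lay outside ribosomal RNA regions and 372290 to 1083774 in protein-coding genes. The labels name 3 biological replicates for each strain and phase, so the p-values reflect the spread between separate cultures of 1 strain. All log2 fold changes and standard errors come from edgeR fits to the counts of all 18 libraries, with 3 libraries in each group and p-values adjusted over the 5031 features. Values beside gene names are log2 fold changes, with the standard error after ±, and list medians are medians of them. A feature is said to rise, fall or change only where its adjusted p passed 0.05, and intervals given for ratios cover counting error only.

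Counts of hfq itself, the gene targeted in the deletion strain, were low in each of its 9 libraries: 10, 18, 9 in exponential, 16, 11, 13 in transition and 13, 10, 15 in stationary phase. The wild-type libraries held 548, 1194, 1123, then 1196, 961, 1013, then 548, 416, 612 counts of hfq in the same order. Its log2 fold change, deletion against wild type, was -6.35 ± 0.34 (adjusted p = 1.66e-11), -5.69 ± 0.33 (adjusted p = 1.32e-11) and -5.12 ± 0.33 (adjusted p = 1.63e-10) in the 3 phases. From exponential to stationary phase hfq also fell in wild type, with a log2 fold change of -2.13 ± 0.26 (adjusted p = 2.36e-07). The gene lies at 5564255 to 5564515 on the minus strand of the chromosome sequence used by the authors, whose version is not given in the sources used here.

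**Figure D1:**
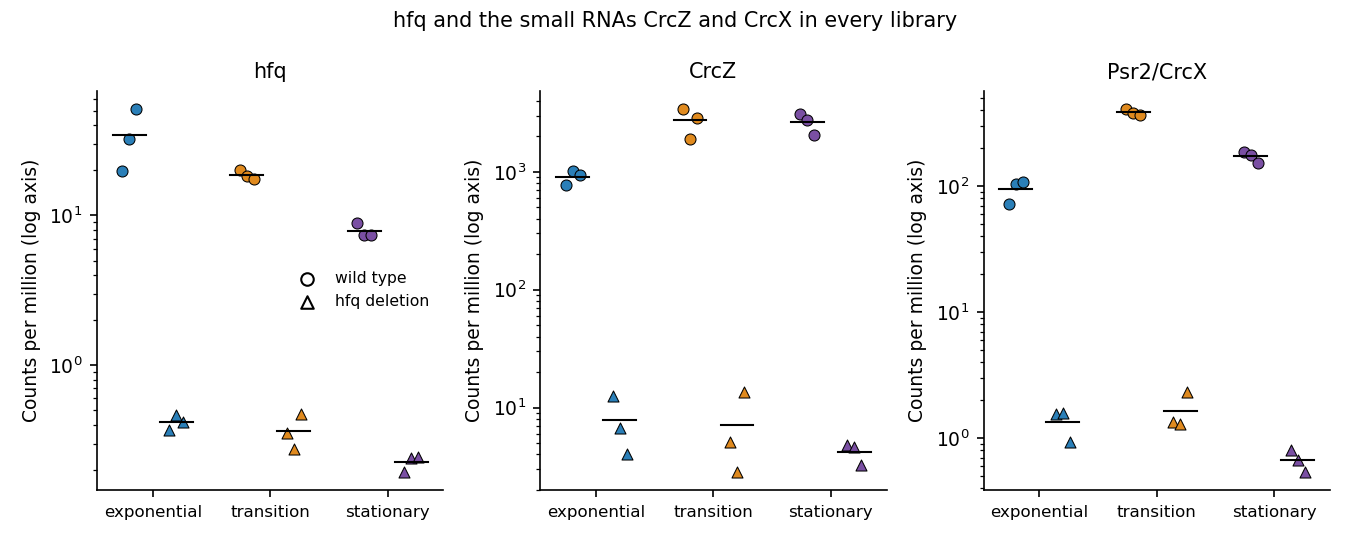
CPM of hfq and of the small RNAs CrcZ and CrcX in each of the 18 libraries, by strain and growth phase.

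Growth phase and strain both separate the libraries. The first principal component of the tested features carries 43.7% of the variance and the second 20.1%. On the first, the wild-type groups have means of -65.6, 32.0 and 55.4 in exponential, transition and stationary phase (n = 3 each), and the deletion groups -49.7, -2.16 and 30.1. Stationary deletion library 2 sits at 42.0 on this component, away from the other two of its group at 22.8 and 25.7.

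**Figure D2:**
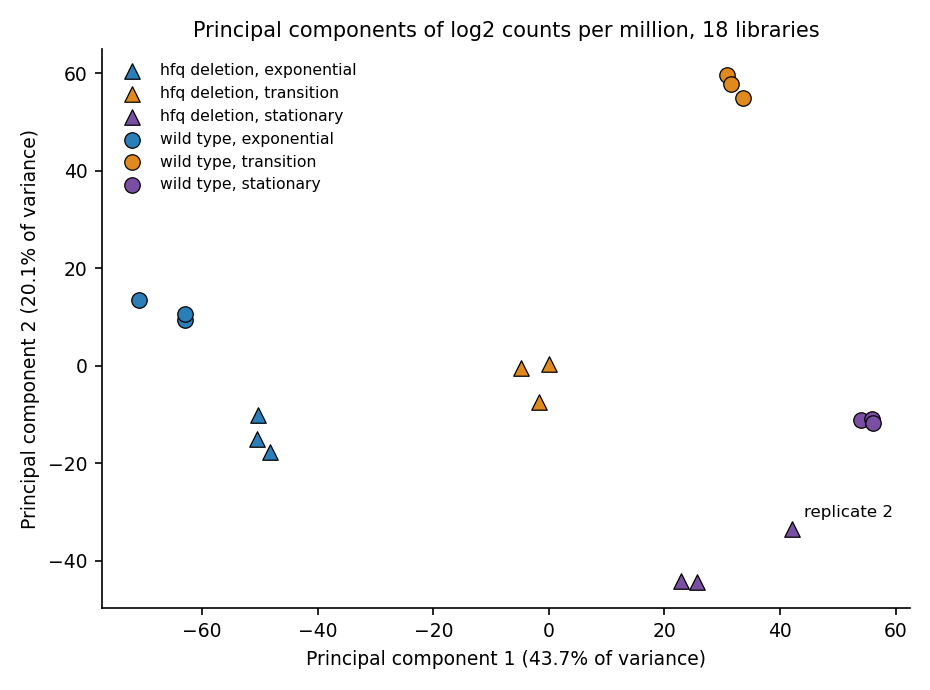
Scores of the 18 libraries on the first 2 principal components, by strain and growth phase.

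Ribosomal RNA regions took a larger share of all counts in the deletion strain, on average 95.3 ± 2.61% against 92.7 ± 2.53% in exponential, 94.9 ± 0.862% against 90.0 ± 1.40% in transition and 89.7 ± 1.93% against 82.7 ± 2.97% in stationary phase (mean ± SD, n = 3, exact p = 0.200, 0.100 and 0.100, where 0.1 is the smallest value that 3 against 3 libraries allow). Known small RNAs went the other way, with 0.824 ± 0.427% against 1.66 ± 0.591%, 1.26 ± 0.384% against 2.67 ± 0.896% and 1.86 ± 0.871% against 6.23 ± 1.34% (exact p = 0.200, 0.100 and 0.100). Of counts outside ribosomal RNA regions they were 17.8 ± 2.57% against 22.98 ± 2.63%, 24.3 ± 3.65% against 26.4 ± 5.20% and 17.5 ± 5.50% against 36.0 ± 2.60% (exact p = 0.200, 0.600 and 0.100), and the strains overlap in exponential and transition phase on this scale. The protein-coding share was 1.08 ± 0.455% against 1.69 ± 0.454%, 1.33 ± 0.206% against 2.07 ± 0.427% and 1.99 ± 0.160% against 2.11 ± 0.400% (exact p = 0.200, 0.100 and 0.8). As a share of counts outside ribosomal RNA regions the direction turned, with 24.7 ± 6.51% in the deletion strain against 23.8 ± 2.78%, 26.4 ± 4.14% against 20.7 ± 2.53% and 19.6 ± 3.19% against 12.2 ± 0.344% (exact p = 1, 0.200 and 0.100). In exponential phase that turn rests on single libraries, with a difference of -2.84 points without deletion exponential 1 and -0.00429 without wild-type exponential 1.

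Between the strains, 1298 of 5031 features changed in exponential phase, 2058 at transition and 1873 in stationary phase. The 3 values of a group lay apart from those of the other for 2038, 2756 and 2335 features (40.5, 54.8 and 46.4%), where 10% are due by chance.

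From PP_3849 to PP_3920, at 4372649 to 4427414 on the chromosome, the deletion strain had almost no counts at any phase. This region of 54.8 kb holds 79 features, 71 protein-coding and 7 RNA beside the maturase PP_3868. Without PP_3868 the region had 48 counts over the 9 deletion libraries and 53774 over the 9 wild-type libraries, which is 0.110% of wild type after scaling by library size. Of its features, 65 had 0 counts in every deletion library and some in wild type. The maturase itself had 1732 and 1294 counts, but it is 1 of 8 copies of equal length whose reads cannot be told apart. The region was looked at after the values were seen. Of its 39 tested features other than PP_3868, 39, 38 and 39 are among the lower features of the 3 strain comparisons.

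**Figure D3:**
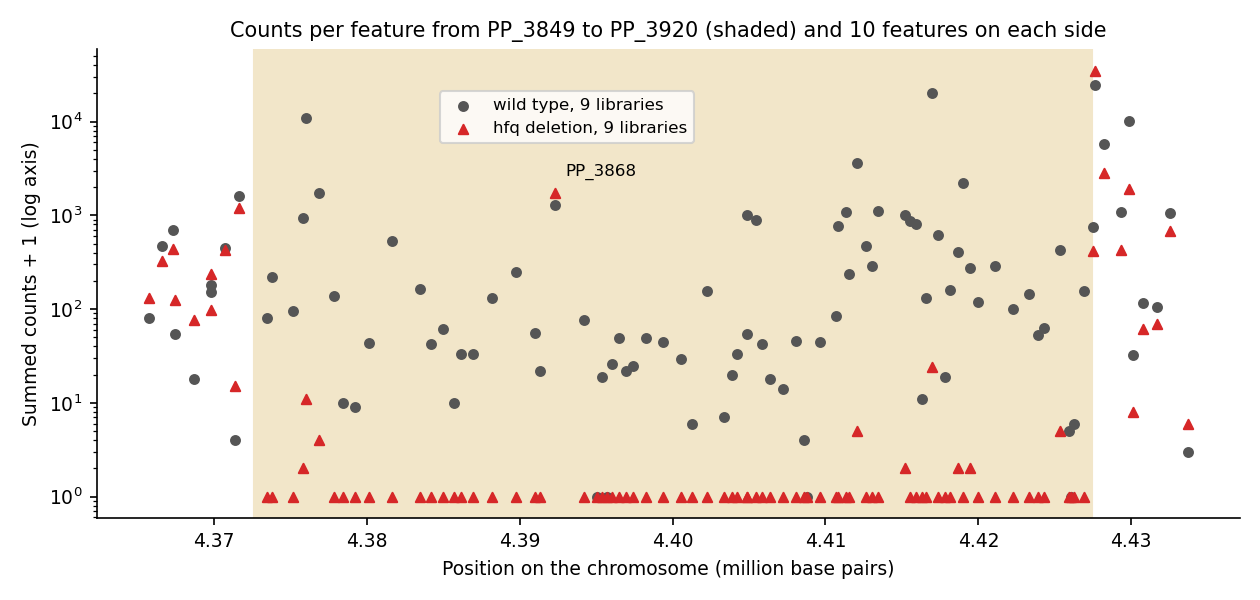
Counts of each feature in and beside the PP_3849 to PP_3920 region, summed over the libraries of each strain.

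In exponential phase the small RNAs CrcZ and CrcX, which hold Hfq and Crc away from their target messages, were among the strongest losses in the deletion strain. CrcZ fell, at -6.87 ± 0.58 (n = 3 against 3, adjusted p = 1.25e-08), from 912 ± 124 to 7.79 ± 4.41 counts per 1000000 counts of a library (CPM), and CrcX at -6.10 ± 0.35 (adjusted p = 3.39e-11). Large increases were also seen for the porin gene oprB-1 at 4.26 ± 0.29 (adjusted p = 5.67e-10), or 44.8 ± 8.66 against 2.32 ± 0.520 CPM, and the transporter genes PP_1018 at 4.15 ± 0.249, PP_1016 at 3.86 ± 0.31 and PP_1017 at 3.79 ± 0.27. Several iron uptake genes fell, among them fpvA for the pyoverdine receptor at -3.87 ± 0.37 (adjusted p = 1.24e-07) and tonB at -3.09 ± 0.29 (adjusted p = 7.67e-08). In all, 533 features rose and 765 fell, with 434 and 380 of them at least 2-fold, but upper-quartile scaling gives 755 higher and 475 lower and the authors' scaling 713 and 511.

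Further increases were PP_4578 (4.14, adjusted p = 2.56e-10), PP_4575 (3.55, adjusted p = 1.72e-08) and PP_4577 (3.44, adjusted p = 7.06e-09), which lie close together, the diguanylate cyclase gene PP_3182 (3.88, adjusted p = 1.30e-04), the integrase gene PP_2297 (3.87, adjusted p = 2.16e-06), the transporter gene PP_1400 (3.80, adjusted p = 0.00207) and rbsC (3.45, adjusted p = 5.24e-10). PP_2675, a cytochrome c-type gene, had the largest estimate at 5.47 ± 1.60 (adjusted p = 0.0240), but was no longer called without deletion exponential 1 (adjusted p = 0.121), wild-type exponential 1 (0.0706), wild-type exponential 2 (0.0815) or wild-type exponential 3 (0.0695) and moved to 3.78 without deletion exponential 1. Among unannotated RNAs Pit192 rose by 5.30 ± 0.37 (adjusted p = 6.30e-10) and Pit216 by 3.10 ± 0.30 (adjusted p = 9.21e-08), and Pat182, antisense to fleQ, by 1.95 ± 0.45 (adjusted p = 0.00425).

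Decreases outside iron uptake included gltP for a glutamate and aspartate symporter (-3.64, adjusted p = 1.28e-09), PP_1083 (-3.54, adjusted p = 3.47e-08), the amino acid carrier gene PP_0496 (-3.01, adjusted p = 1.02e-08) and the antisense RNA AS9 (-3.798, adjusted p = 5.02e-07). The histone-like gene hupN fell, at -2.72 ± 0.43 (adjusted p = 1.03e-04), or -1.92 without wild-type exponential 3, and PP_0862 fell, at -2.61 ± 0.31 (adjusted p = 1.80e-06), or -3.20 without deletion exponential 2. In the PP_3849 to PP_3920 region, PP_3896 had 2 counts against 1049, a ratio of 0.00189 (95% interval 2.28e-04 to 0.00684), and the small RNA Pit139 had 0 against 633, at least 213-fold lower.

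Of the known small RNAs, 0 rose, 7 fell and 6 did not pass (0 and 7 adjusted over the list alone, median -1.86, camera adjusted p = 5.85e-06 and adjusted p = 0.234 with an estimated correlation). Beyond CrcZ and CrcX, the iron-responsive Prrf2 fell, at -2.89 ± 0.35 (adjusted p = 2.17e-06), the Spot42-like RNA at -2.18 ± 0.40 (adjusted p = 3.86e-04) and PhrS at -1.86 ± 0.35 (adjusted p = 4.52e-04). PrrF1 fell, at -2.06 ± 0.38 (adjusted p = 4.37e-04), or -2.67 without deletion exponential 2, while RgsA at -2.44 ± 0.76 (adjusted p = 0.0254) was no longer called without deletion exponential 1 (adjusted p = 0.102), deletion exponential 2 (0.0527), wild-type exponential 1 (0.0680) or wild-type exponential 2 (0.0593). RsmY (-0.83, adjusted p = 0.105), RsmZ (-0.38, adjusted p = 0.576), 6S RNA (-0.74, adjusted p = 0.133), tmRNA (-0.60, adjusted p = 0.2499), SRP RNA (-0.57, adjusted p = 0.345) and RnpB (0.03, adjusted p = 0.970) did not pass, nor did crc (-0.29, adjusted p = 0.336) or rpoS (0.14, adjusted p = 0.730). The gene cbrB is not reported here.

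Gene lists were fixed as patterns before any count was seen, and wrong matches were corrected after the table was read. They were counted and tested with camera, and 8 of 31 passed in exponential phase. Among the 54 ribosomal protein genes 0 rose, 15 fell and 39 did not pass (0 and 15 adjusted over the list alone). Among them were rpmH -1.86 and rpsU -1.68 (median -0.42, camera adjusted p = 0.00596 and adjusted p = 0.573 with an estimated correlation). Of 13 translation factor genes 0 rose, 6 fell and 7 did not pass (0 and 6 adjusted over the list alone). Among them were prfC -1.08 and infA -1.29 (median -0.56, camera adjusted p = 0.0102 and adjusted p = 0.229 with an estimated correlation). For ATP synthase 0 rose, 6 fell and 3 did not pass (0 and 8 adjusted over the list alone). Among them were atpC -1.77 and atpA -1.04 (median -0.87, camera adjusted p = 0.00177 and adjusted p = 0.229 with an estimated correlation). All NADH dehydrogenase genes pointed down and 0 rose, 10 fell and 3 did not pass (0 and 13 adjusted over the list alone). Among them were nuoI -1.62 and nuoL -1.21 (median -0.93, camera adjusted p = 3.45e-05 and adjusted p = 0.362 with an estimated correlation).

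Genes for the catabolism of aromatic compounds and amino acids went up: 18 rose, 2 fell and 34 did not pass (19 and 2 adjusted over the list alone). Among them were ivd 2.01, bkdA2 2.01 and lpdV 1.87 (median 0.69, camera adjusted p = 1.38e-06 and adjusted p = 0.0218 with an estimated correlation). This is the single list of the comparison that kept its call with an estimated correlation. Of the transposase genes 8 rose, 0 fell and 48 did not pass (8 and 0 adjusted over the list alone, median 0.19, camera adjusted p = 8.49e-04 and adjusted p = 0.446 with an estimated correlation), though many are copies whose reads cannot be told apart. Among other predicted RNAs 4 rose, 13 fell and 33 did not pass (4 and 13 adjusted over the list alone, median -0.41, camera adjusted p = 0.01003 and adjusted p = 0.572 with an estimated correlation).

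The remaining lists did not pass camera. In the hfq neighbourhood 2 rose, 5 fell and 2 did not pass (2 and 5 adjusted over the list alone, median -0.54, camera adjusted p = 0.301). Those that fell include hfq itself. The gene downstream of it, hflX, rose by 1.29 ± 0.24 (adjusted p = 3.68e-04). For terminal oxidases 0 rose, 0 fell and 14 did not pass (0 and 0 adjusted over the list alone, median -0.09, test direction up, camera adjusted p = 0.974, and a median of 0.10 with upper-quartile scaling). For the TCA cycle 0 rose, 3 fell and 16 did not pass (0 and 3 adjusted over the list alone, median -0.19, camera adjusted p = 0.514, and a median of 0.00 with upper-quartile scaling). In the list of glucose and Entner-Doudoroff genes 2 rose, 3 fell and 22 did not pass (2 and 3 adjusted over the list alone, median 0.04, mean -0.03, test direction up, camera adjusted p = 0.664), with gntP -1.91 and gltR-1 -2.16. Flagellum genes split so that 2 rose, 7 fell and 34 did not pass (2 and 7 adjusted over the list alone, median -0.24, camera adjusted p = 0.273), and chemotaxis genes so that 7 rose, 2 fell and 34 did not pass (6 and 2 adjusted over the list alone, median 0.07, camera adjusted p = 0.151). For pili 1 rose, 3 fell and 14 did not pass (1 and 2 adjusted over the list alone, median -0.38, camera adjusted p = 0.514). Surface adhesin and exopolysaccharide genes included algN 1.91, algU 1.85 and mucA 1.73, and 3 rose, 1 fell and 14 did not pass (3 and 1 adjusted over the list alone, median -0.17, mean 0.11, test direction up, camera adjusted p = 0.387, and a median of 0.02 with upper-quartile scaling).

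Among cyclic di-GMP enzymes 5 rose, 2 fell and 24 did not pass (5 and 2 adjusted over the list alone, median 0.06, camera adjusted p = 0.579). For general stress and stationary phase 1 rose, 3 fell and 18 did not pass (1 and 3 adjusted over the list alone, median -0.08, camera adjusted p = 0.974, and a median of 0.11 with upper-quartile scaling). Chaperones and heat shock genes: 1 rose, 2 fell and 23 did not pass (1 and 2 adjusted over the list alone, median 0.10, camera adjusted p = 0.277). In the oxidative stress list ahpC rose by 2.56 ± 0.30 (adjusted p = 1.49e-06), and 2 rose, 2 fell and 12 did not pass (2 and 2 adjusted over the list alone, median -0.02, mean 0.15, test direction up, camera adjusted p = 0.664, and a median of 0.17 with upper-quartile scaling). Siderophore and iron uptake genes included fecA -5.33 and exbD -2.68, and 0 rose, 7 fell and 26 did not pass (0 and 7 adjusted over the list alone, median -0.36, camera adjusted p = 0.0549). For polyhydroxyalkanoate 0 rose, 0 fell and 5 did not pass (0 and 0 adjusted over the list alone, median 0.32, camera adjusted p = 0.372). For efflux pumps 6 rose, 3 fell and 20 did not pass (6 and 3 adjusted over the list alone, median 0.38, camera adjusted p = 0.0937), with mexF 2.15 and ttgR 1.51. RNA turnover genes and RNA-binding regulators: 1 rose, 7 fell and 13 did not pass (1 and 7 adjusted over the list alone, median -0.35, camera adjusted p = 0.112). Those that fell include hfq itself.

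For prophage genes 5 rose, 8 fell and 23 did not pass (6 and 8 adjusted over the list alone, median 0.45, mean -0.57, test direction up, camera adjusted p = 0.295). Of those that fell, 6 lie in the PP_3849 to PP_3920 region, and among the 30 tested prophage genes elsewhere, looked at after the values were seen, 5 rose and 2 fell (median 0.61). Amino acid and peptide ABC transport genes: 19 rose, 17 fell and 61 did not pass (21 and 18 adjusted over the list alone, median 0.10, camera adjusted p = 0.277), with dppD 2.29 and sdaC -2.07. For the SOS response 5 rose, 2 fell and 2 did not pass (5 and 2 adjusted over the list alone, median 0.72, camera adjusted p = 0.0861), with lexA-1 1.25 and uvrA -0.83. Intergenic small RNAs: 20 rose, 42 fell and 169 did not pass (23 and 43 adjusted over the list alone, median -0.31, camera adjusted p = 0.112). For antisense RNAs 6 rose, 7 fell and 89 did not pass (6 and 7 adjusted over the list alone, median -0.18, camera adjusted p = 0.809, and a median of 0.005 with upper-quartile scaling). The intergenic and antisense lists both include features of the PP_3849 to PP_3920 region. In tRNA-overlapping regions 0 rose, 0 fell and 10 did not pass (0 and 0 adjusted over the list alone, median -0.54, camera adjusted p = 0.277), and in rRNA regions 0 rose, 0 fell and 8 did not pass (0 and 0 adjusted over the list alone, median 0.27, camera adjusted p = 0.295). The arginine deiminase pathway, with 4 members too small to test, had 0 higher and 0 lower (0 and 0 adjusted over the list alone).

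**Figure D4:**
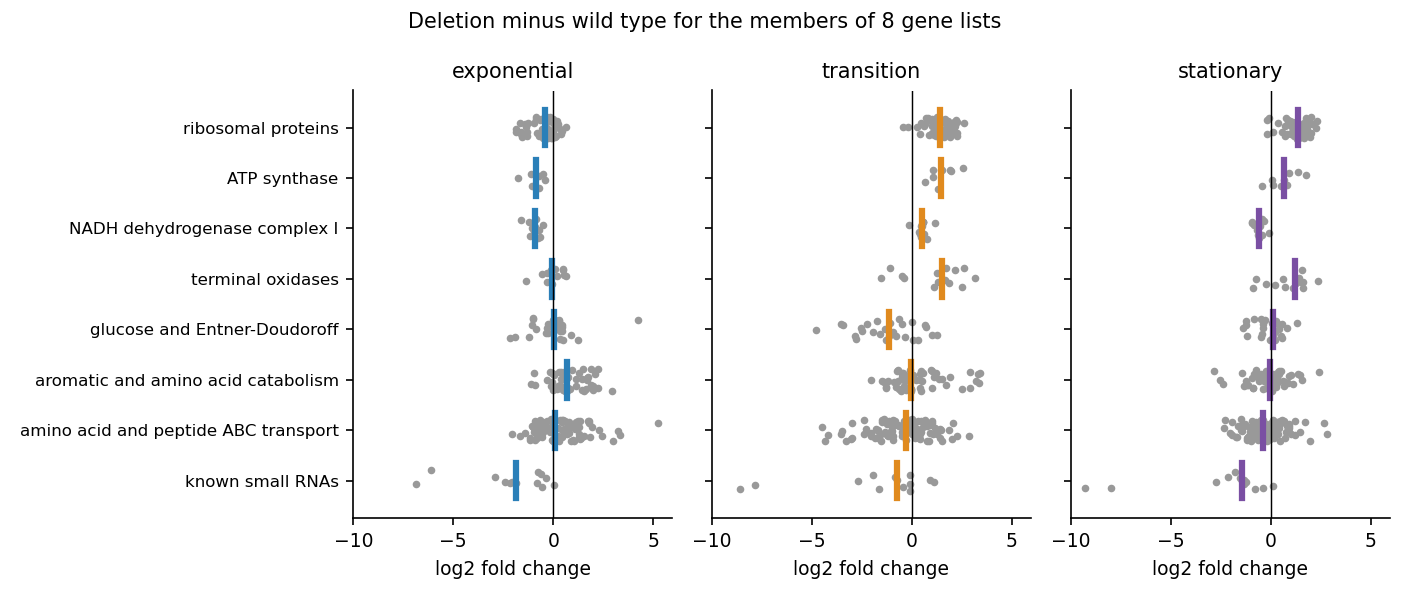
Log2 fold change, deletion against wild type, of every tested member of 8 lists in the 3 growth phases.

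At transition phase the cytochrome c-type gene PP_3332 rose most among annotated genes in the deletion strain, by 6.46 ± 0.33 (adjusted p = 1.80e-12), or 28.9 ± 2.84 against 0.330 ± 0.129 CPM (n = 3). The aspartase gene aspA rose by 4.61 ± 0.30 (adjusted p = 4.90e-11), and ssuE and lsfA, neighbours linked to sulfonate use, by 5.93 ± 0.56 and 4.71 ± 0.55. CrcX fell, at -7.87 ± 0.37 (adjusted p = 1.38e-12) and CrcZ at -8.60 ± 0.62 (adjusted p = 3.29e-10), or -9.43 without deletion transition 3. Large decreases were also seen for PP_0308 at -6.43 ± 0.39, PP_0310 at -6.08 ± 0.33, PP_0311 at -5.93 ± 0.51, glyA-1 at -5.83 ± 0.36 and soxB for sarcosine oxidase at -6.23 ± 0.43. Here 1032 features rose and 1026 fell, 722 and 669 of them at least 2-fold, and among the 414 RNAs 45 rose and 128 fell.

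Other increases were PP_1110 (4.74, adjusted p = 7.50e-06), PP_1111 (4.49, adjusted p = 9.00e-07) and PP_1112 (4.63, adjusted p = 2.83e-06), which are adjacent, the chaperone-associated PP_3095 (3.70, adjusted p = 2.81e-09), the phosphate transport gene PP_2656 (3.595, adjusted p = 5.84e-04), PP_4108 (3.47, adjusted p = 9.80e-08), paaA of phenylacetate breakdown (3.42, adjusted p = 2.57e-10) and ipk (3.36, adjusted p = 4.60e-07). PP_1017 fell, at -5.91 ± 0.34 (adjusted p = 1.28e-11) after its rise in exponential phase, and PP_3379 fell, at -6.49 ± 0.56 (adjusted p = 2.33e-08), or -5.80 without deletion transition 1 and -7.77 without deletion transition 2. In the PP_3849 to PP_3920 region hicB-2 had 0 against 423 counts, at least 93.9-fold lower, hicA-2 had 0 against 301 counts, at least 66.8-fold lower, and PP_3896 had a ratio of 9.79e-04 (2.48e-05 to 0.00546). The unannotated RNAs Pit218 and Pit192 rose by 4.02 ± 0.54 and 2.76 ± 0.32, while the antisense RNA AS2 had 0 against 2727 counts, at least 605-fold lower.

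Of the known small RNAs 2 rose, 5 fell and 6 did not pass (2 and 5 adjusted over the list alone, median -0.75, camera adjusted p = 0.0171 and adjusted p = 0.506 with an estimated correlation). Prrf2 fell, at -2.70 ± 0.34 (adjusted p = 1.17e-06), PrrF1 at -1.97 ± 0.39 (adjusted p = 3.71e-04) and RgsA at -1.66 ± 0.49 (adjusted p = 0.0116). RsmZ rose by 1.12 ± 0.44 (adjusted p = 0.0472) and PhrS by 0.88 ± 0.34 (adjusted p = 0.0411), but RsmZ was no longer called without deletion transition 1 (adjusted p = 0.111), deletion transition 2 (0.0598), deletion transition 3 (0.0952), wild-type transition 1 (0.150) or wild-type transition 2 (0.153), and PhrS was no longer called without deletion transition 2 (adjusted p = 0.0615), deletion transition 3 (0.170), wild-type transition 1 (0.192) or wild-type transition 2 (0.140) and moved to 1.47 without wild-type transition 3. The Spot42-like RNA (-0.44, adjusted p = 0.371), RsmY (-0.12, adjusted p = 0.827), 6S RNA (-0.75, adjusted p = 0.0993), tmRNA (-0.12, adjusted p = 0.822), SRP RNA (-0.86, adjusted p = 0.109) and RnpB (-0.12, adjusted p = 0.823) did not pass, and neither did crc (-0.26, adjusted p = 0.344) or rpoS (-0.55, adjusted p = 0.0751).

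Ribosomal protein genes were higher in the deletion strain at transition phase, opposite to their median in exponential phase: 47 rose, 0 fell and 7 did not pass (47 and 0 adjusted over the list alone). Among them were rpsJ 2.11 and rplU 2.62 (median 1.42, camera adjusted p = 1.33e-14 and adjusted p = 0.157 with an estimated correlation). Translation factor genes went with them, and 8 rose, 0 fell and 5 did not pass (8 and 0 adjusted over the list alone). Among them were infA 2.19 and tsf 2.04 (median 0.97, camera adjusted p = 0.00568 and adjusted p = 0.148 with an estimated correlation). All ATP synthase genes rose: 9 rose, 0 fell and 0 did not pass (9 and 0 adjusted over the list alone). Among them were atpB 1.96 and atpE 2.55 (median 1.45, camera adjusted p = 2.78e-05 and adjusted p = 0.110 with an estimated correlation). For terminal oxidases 10 rose, 3 fell and 1 did not pass (10 and 3 adjusted over the list alone). Among them were ccoN-1 2.51, ccoP-1 2.58 and cyoD 1.84 (median 1.48, camera adjusted p = 0.00218 and adjusted p = 0.167 with an estimated correlation). Flagellum genes divided, and 17 rose, 5 fell and 21 did not pass (18 and 5 adjusted over the list alone). Among them were fliE 1.39 and motC 1.08 (median 0.45, camera adjusted p = 0.0232 and adjusted p = 0.554 with an estimated correlation). Of chaperone and heat shock genes 13 rose, 2 fell and 11 did not pass (13 and 3 adjusted over the list alone). Among them were grpE 2.51, hslU 1.99 and ibpA 1.89 (median 0.55, camera adjusted p = 0.00568 and adjusted p = 0.418 with an estimated correlation).

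Glucose and Entner-Doudoroff genes leaned down at transition phase: 2 rose, 15 fell and 10 did not pass (2 and 16 adjusted over the list alone). Among them were oprB-1 -3.46, zwf-1 -2.84, ptxS -2.83 and pgl -2.51 (median -1.14, camera adjusted p = 5.13e-05 and adjusted p = 0.110 with an estimated correlation). Of amino acid and peptide ABC transport genes 20 rose, 39 fell and 38 did not pass (21 and 40 adjusted over the list alone). Among them were aapJ -4.48, aapM -4.36 and aapQ -4.21 (median -0.32, camera adjusted p = 0.0233 and adjusted p = 0.167 with an estimated correlation). Intergenic small RNAs leaned down, since 23 rose, 68 fell and 140 did not pass (23 and 68 adjusted over the list alone). Among them were Pit156 -4.04 and Pit199 -3.12 (median -0.33, camera adjusted p = 0.0164 and adjusted p = 0.648 with an estimated correlation), and so did antisense RNAs, where 9 rose, 37 fell and 56 did not pass (10 and 42 adjusted over the list alone, median -0.59, camera adjusted p = 0.00616 and adjusted p = 0.418 with an estimated correlation). Both RNA lists include features of the PP_3849 to PP_3920 region, and they were not tested without them. Downstream of hfq, hflX rose by 1.79 ± 0.24 (adjusted p = 3.00e-06). In total 11 of 31 lists passed, none with an estimated correlation.

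In stationary phase the acetoin catabolism genes acoA and acoC rose in the deletion strain by 5.55 ± 0.49 (adjusted p = 5.32e-08) and 5.10 ± 0.40 (adjusted p = 4.14e-09), acoA from 0.0600 ± 0.0113 to 2.95 ± 1.60 CPM (n = 3). Next to these, PP_0556 rose by 6.45 ± 0.71, or 7.69 without wild-type stationary 2 and 5.82 without wild-type stationary 3, acoB by 6.16 ± 0.75, or 6.92 without wild-type stationary 3, and adh by 2.85 ± 0.37, or 2.26 without deletion stationary 2. CrcZ fell, at -9.28 ± 0.64 (adjusted p = 4.94e-10) and CrcX at -7.998 ± 0.38 (adjusted p = 1.26e-12). The tyrosine breakdown genes PP_4619 and PP_4620 fell, at -4.86 ± 0.48 (adjusted p = 3.88e-07) and -3.67 ± 0.33 (adjusted p = 5.17e-08). In total 961 features rose and 912 fell, 574 and 545 of them at least 2-fold.

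PP_3658 (3.02, adjusted p = 1.63e-10), the regulator gene agmR (2.60, adjusted p = 5.64e-06), PP_3491 (2.57, adjusted p = 1.65e-05), PP_4636 (2.56, adjusted p = 6.19e-08), PP_3332 (2.52, adjusted p = 2.35e-07) and PP_0862 (2.50, adjusted p = 1.30e-06) also rose, and PP_1064 fell (-3.03, adjusted p = 1.47e-07). The citrate transporter gene PP_3074 rose by 3.41 ± 0.61 (adjusted p = 4.96e-04), or 1.92 without deletion stationary 2, and PP_3807 fell, at -2.80 ± 0.36 (adjusted p = 6.50e-06), or -3.47 without deletion stationary 2. In the PP_3849 to PP_3920 region hicB-2 had 0 against 470 counts, at least 133-fold lower, PP_3905 had 0 against 426 counts, at least 120.2-fold lower, and Pit221 had 1 count against 7152, a ratio of 1.65e-04 (4.18e-06 to 9.21e-04). Among unannotated RNAs t44 rose by 2.41 ± 0.30 (adjusted p = 3.15e-06) and Pat175, antisense to sucA, by 2.98 ± 0.30 (adjusted p = 1.37e-07).

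No known small RNA rose in stationary phase: 0 rose, 10 fell and 3 did not pass (0 and 11 adjusted over the list alone, median -1.43, camera adjusted p = 1.36e-05 and adjusted p = 0.245 with an estimated correlation). Prrf2 fell, at -2.77 ± 0.31 (adjusted p = 7.58e-07), PrrF1 at -1.43 ± 0.33 (adjusted p = 0.00213), the Spot42-like RNA at -1.55 ± 0.39 (adjusted p = 0.00373), RsmY, which binds Csr-family proteins, at -2.16 ± 0.39 (adjusted p = 1.87e-04) and tmRNA at -1.32 ± 0.38 (adjusted p = 0.00872). RgsA fell, at -1.79 ± 0.45 (adjusted p = 0.00501), or -2.86 without deletion stationary 2. RsmZ fell, at -1.37 ± 0.45 (adjusted p = 0.0196), and it was no longer called without deletion stationary 1 (adjusted p = 0.0949), deletion stationary 3 (0.103), wild-type stationary 2 (0.0595) or wild-type stationary 3 (0.0691) and moved to -2.17 without deletion stationary 2. SRP RNA fell, at -1.22 ± 0.43 (adjusted p = 0.0293), and it was no longer called without deletion stationary 1 (adjusted p = 0.102), deletion stationary 3 (0.0851), wild-type stationary 2 (0.0941) or wild-type stationary 3 (0.0635). PhrS (-0.38, adjusted p = 0.391), 6S RNA (0.12, adjusted p = 0.833) and RnpB (-0.803, adjusted p = 0.0869) did not pass.

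The sigma factor gene rpoS fell, at -0.78 ± 0.24 (adjusted p = 0.0149) in stationary phase, and it was no longer called without deletion stationary 3 (adjusted p = 0.0570). The gene crc rose by 0.66 ± 0.21 (adjusted p = 0.0201), and it was no longer called without wild-type stationary 2 (adjusted p = 0.0518) or wild-type stationary 3 (0.0738). Near hfq, hflX rose by 2.21 ± 0.24 (adjusted p = 5.73e-07).

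Ribosomal protein genes stayed higher in the deletion strain: 45 rose, 0 fell and 9 did not pass (47 and 0 adjusted over the list alone). Among them were rpsJ 2.25, rpmH 2.29 and rpsL 1.86 (median 1.38, camera adjusted p = 1.33e-16 and adjusted p = 0.227 with an estimated correlation). For translation factors 9 rose, 0 fell and 4 did not pass (9 and 1 adjusted over the list alone). Among them were tsf at 1.97 ± 0.30 (median 0.97, camera adjusted p = 9.83e-04 and adjusted p = 0.171 with an estimated correlation). Of terminal oxidase genes 9 rose, 1 fell and 4 did not pass (9 and 2 adjusted over the list alone). Among them were cyoA 2.33 and ccoN-1 1.498 (median 1.20, camera adjusted p = 0.00370 and adjusted p = 0.245 with an estimated correlation). NADH dehydrogenase genes leaned down, and 0 rose, 3 fell and 10 did not pass (0 and 2 adjusted over the list alone). Among them were nuoH at -0.92 ± 0.21 (median -0.60, camera adjusted p = 0.0199 and adjusted p = 0.784 with an estimated correlation). For the flagellum 16 rose, 4 fell and 23 did not pass (17 and 5 adjusted over the list alone). Among them were fliD 1.53, fliL 1.59 and flgC 1.72 (median 0.30, camera adjusted p = 0.0199 and adjusted p = 0.784 with an estimated correlation).

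Among lists short of a call in stationary phase, TCA cycle genes gave the following: 8 rose, 4 fell and 7 did not pass (8 and 4 adjusted over the list alone, median 0.38, camera adjusted p = 0.0851), with sdhC 2.30 and gltA 1.53. Catabolism of aromatic compounds and amino acids: 8 rose, 13 fell and 33 did not pass (8 and 13 adjusted over the list alone, median -0.04, camera adjusted p = 0.773), with hmgA at -2.54 ± 0.32. In this comparison 7 of 31 lists passed, not all of which are described above, and none passed with an estimated correlation.

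The effect of the deletion, meaning here the difference between the strains, was more alike between transition and stationary phase than between either and exponential phase. For transition and stationary phase, 723 features changed in the same direction and 216 in opposite ones, with 404 higher in both (197 expected by chance) and 319 lower in both (186 expected). Exponential and transition phase shared 328 in the same and 295 in opposite directions, and exponential and stationary phase 364 and 225. Outside the PP_3849 to PP_3920 region these counts were 685 and 216, 290 and 295, and 325 and 225. The gene hflX rose and Prrf2, PrrF1, CrcZ and CrcX fell in all 3 phases.

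From exponential to transition phase in wild type, the glycolate oxidase gene glcD rose by 6.86 ± 0.44 (adjusted p = 2.94e-11), or 41.6 ± 10.3 against 0.351 ± 0.0902 CPM (n = 3), and the nucleoside transporter gene PP_0709 by 6.37 ± 0.35 (adjusted p = 4.44e-12). Genes of the translation machinery fell, led by infA at -5.96 ± 0.36 (adjusted p = 1.14e-11), rpsT at -5.34 ± 0.42 (adjusted p = 4.58e-10) and rpmH at -5.28 ± 0.32 (adjusted p = 1.19e-11). Other large decreases were aspA (-5.33, adjusted p = 5.78e-12), sdaC (-5.25, adjusted p = 8.68e-12), PP_0496 (-5.07, adjusted p = 4.01e-12) and PP_3992 (-4.98, adjusted p = 7.24e-11). In all 1615 features rose and 1551 fell, and the median of all features was 0.12 against 0.30 with upper-quartile scaling.

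Every ribosomal protein gene fell on the way to transition phase: 0 rose, 54 fell and 0 did not pass (0 and 54 adjusted over the list alone). Among them were rplI -3.93 and rpsU -4.54 (median -3.31, camera adjusted p = 5.99e-23 and adjusted p = 0.0354 with an estimated correlation). For translation factors 1 rose, 11 fell and 1 did not pass (1 and 11 adjusted over the list alone, median -3.10, camera adjusted p = 1.79e-05 and adjusted p = 0.0186 with an estimated correlation), and for ATP synthase 0 rose, 9 fell and 0 did not pass (0 and 9 adjusted over the list alone). Among them were atpC -4.37 and atpB -3.54 (median -3.21, camera adjusted p = 3.67e-06 and adjusted p = 0.0186 with an estimated correlation). NADH dehydrogenase genes followed, and 0 rose, 13 fell and 0 did not pass (0 and 13 adjusted over the list alone). Among them were nuoH -2.28 and nuoI -3.23 (median -1.89, camera adjusted p = 2.38e-05 and adjusted p = 0.294 with an estimated correlation). Of flagellum genes 5 rose, 30 fell and 8 did not pass (6 and 31 adjusted over the list alone). Among them were fliE -3.10 and flgA -2.60 (median -1.23, camera adjusted p = 4.27e-05 and adjusted p = 0.277 with an estimated correlation). Catabolism of aromatic compounds and amino acids went up, and 31 rose, 4 fell and 19 did not pass (31 and 4 adjusted over the list alone). Among them were hutI 4.37, hutU 3.85 and paaH 4.39 (median 1.37, camera adjusted p = 1.65e-05 and adjusted p = 0.0186 with an estimated correlation). Amino acid and peptide ABC transport genes leaned the same way: 56 rose, 11 fell and 30 did not pass (58 and 13 adjusted over the list alone). Among them were PP_3595 4.89 and aapM 5.06 (median 1.31, camera adjusted p = 4.66e-05 and adjusted p = 0.0186 with an estimated correlation). General stress genes included rpoS at 2.13 ± 0.26 (adjusted p = 2.39e-07), and 11 rose, 2 fell and 9 did not pass (11 and 2 adjusted over the list alone, median 0.95, camera adjusted p = 0.0479 and adjusted p = 0.320 with an estimated correlation).

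From transition to stationary phase in wild type, the small RNA RsmZ rose by 5.35 ± 0.53 (adjusted p = 3.17e-08), or 18352 ± 3181 against 449.6 ± 223 CPM (n = 3). Genes fumC and sodA, whose products work without iron, rose by 5.42 ± 0.31 (adjusted p = 5.34e-12) and 5.32 ± 0.36 (adjusted p = 1.24e-10), and the phosphate transport gene PP_2658 by 5.68 ± 0.82 (adjusted p = 4.21e-05). Type II secretion gene xcpP had 355 counts against 0, at least 99.8-fold higher. The sugar uptake genes PP_1015, PP_1016 and PP_1017 fell, at -5.84 ± 0.29, -6.77 ± 0.39 and -5.87 ± 0.32, and PP_0709 fell, at -6.00 ± 0.32 (adjusted p = 2.39e-12). In all 1160 features rose and 1216 fell.

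Glucose and Entner-Doudoroff genes leaned down into stationary phase: 6 rose, 16 fell and 5 did not pass (6 and 16 adjusted over the list alone). Among them were zwf-1 -3.98, pgl -2.94 and eda -2.92 (median -1.33, camera adjusted p = 0.00452 and adjusted p = 0.164 with an estimated correlation). Of amino acid and peptide ABC transport genes 13 rose, 50 fell and 34 did not pass (13 and 51 adjusted over the list alone). Among them were PP_5031 -4.48 and gabP 3.33 (median -0.73, camera adjusted p = 1.39e-04 and adjusted p = 0.0412 with an estimated correlation). Terminal oxidase genes leaned up: 10 rose, 0 fell and 4 did not pass (10 and 0 adjusted over the list alone). Among them were cioA 2.69 and ccoO-2 1.77 (median 0.90, camera adjusted p = 0.00114 and adjusted p = 0.121 with an estimated correlation). Siderophore and iron uptake genes leaned up as well: 13 rose, 4 fell and 16 did not pass (13 and 4 adjusted over the list alone). Among them were ppsD 3.53 and tonB 2.20 (median 0.49, camera adjusted p = 0.0166 and adjusted p = 0.121 with an estimated correlation).

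Over the whole course from exponential to stationary phase in wild type, RsmZ rose by 5.75 ± 0.54 (adjusted p = 5.09e-09) and the pilus-like genes csuD and PP_2357 by 5.74 ± 0.61 (adjusted p = 1.42e-07) and 5.93 ± 0.59 (adjusted p = 6.88e-08). The polysaccharide genes PP_3132 and PP_3140 rose by 5.48 ± 0.28 (adjusted p = 1.55e-12) and 5.51 ± 0.35 (adjusted p = 2.15e-11). The ribosomal protein genes rpmH, rpmE and rpsT fell, at -7.15 ± 0.36, -6.57 ± 0.41 and -6.00 ± 0.43, rpmE to 7.48 ± 0.366 against 712 ± 149.9 CPM (n = 3). Of 54 ribosomal protein genes 0 rose, 54 fell and 0 did not pass (0 and 54 adjusted over the list alone, median -3.45, camera adjusted p = 7.83e-21 and adjusted p = 0.0779 with an estimated correlation). For chaperones 6 rose, 16 fell and 4 did not pass (6 and 16 adjusted over the list alone). Among them were grpE -4.45 and hslU -3.39 (median -1.16, camera adjusted p = 0.0428 and adjusted p = 0.463 with an estimated correlation). Of known small RNAs 6 rose, 0 fell and 7 did not pass (6 and 0 adjusted over the list alone). Among them were Prrf2 3.53, PrrF1 2.63 and RgsA 4.09 (median 0.70, camera adjusted p = 0.0428 and adjusted p = 0.475 with an estimated correlation). In all 1632 features rose and 1706 fell, and the median of all features was 0.03 against 0.22 with upper-quartile scaling.

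From exponential to transition phase in the deletion strain, paaA rose by 4.03 ± 0.28 (adjusted p = 5.50e-10), the phosphate transporter gene PP_4103 by 4.01 ± 0.34 (adjusted p = 1.14e-08) and PP_3332 by 3.85 ± 0.28 (adjusted p = 1.19e-09). The sugar uptake genes PP_1015, PP_1016, PP_1017, PP_1018 and oprB-1 fell, at -5.73 ± 0.29, -6.76 ± 0.38, -7.10 ± 0.35, -5.66 ± 0.28 and -4.68 ± 0.30, oprB-1 to 1.76 ± 0.679 against 44.8 ± 8.66 CPM (n = 3). Of ribosomal protein genes 0 rose, 50 fell and 4 did not pass (0 and 52 adjusted over the list alone). Among them were rplI -2.01 and rpsS -1.99 (median -1.47, camera adjusted p = 1.48e-20 and adjusted p = 0.0690 with an estimated correlation). For ATP synthase 0 rose, 5 fell and 4 did not pass (0 and 6 adjusted over the list alone). Among them were atpC -1.31 and atpB -1.15 (median -0.72, camera adjusted p = 0.00660 and adjusted p = 0.171 with an estimated correlation). Of glucose and Entner-Doudoroff genes 6 rose, 11 fell and 10 did not pass (7 and 11 adjusted over the list alone). Among them were zwf-1 -3.47 and eda -3.35 (median -0.47, camera adjusted p = 0.0160 and adjusted p = 0.259 with an estimated correlation). Catabolism of aromatic compounds and amino acids leaned up: 21 rose, 3 fell and 30 did not pass (22 and 4 adjusted over the list alone). Among them were hutI 2.77 and paaC 3.71 (median 0.54, camera adjusted p = 1.16e-05 and adjusted p = 0.0478 with an estimated correlation). For general stress 15 rose, 0 fell and 7 did not pass (15 and 0 adjusted over the list alone). Among them were PP_2648 3.31 and rpoS 1.44 (median 1.32, camera adjusted p = 8.43e-05 and adjusted p = 0.0690 with an estimated correlation). In all 869 features rose and 978 fell.

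From transition to stationary phase in the deletion strain, PP_1400 rose by 5.17 ± 0.803 (adjusted p = 1.07e-04), the magnesium transport gene mgtC by 4.66 ± 0.49 (adjusted p = 5.92e-07) and PrrF1 by 4.13 ± 0.40 (adjusted p = 6.46e-08). The histidine breakdown genes hutG, hutI and hutU fell, at -4.79 ± 0.27, -4.50 ± 0.23 and -4.25 ± 0.24, as did paaA at -5.50 ± 0.29 and PP_4619 at -5.56 ± 0.49 (n = 3). In the catabolism list 7 rose, 22 fell and 25 did not pass (8 and 22 adjusted over the list alone, median -0.13, camera adjusted p = 6.53e-04 and adjusted p = 0.0785 with an estimated correlation). Of chaperones and heat shock genes 4 rose, 15 fell and 7 did not pass (4 and 16 adjusted over the list alone). Among them were hslU -3.55, htpG -3.31 and lon-1 -3.12 (median -0.77, camera adjusted p = 2.02e-04 and adjusted p = 0.287 with an estimated correlation). NADH dehydrogenase genes leaned down: 0 rose, 11 fell and 2 did not pass (0 and 11 adjusted over the list alone). Among them were nuoH -1.23 and nuoN -1.64 (median -1.23, camera adjusted p = 2.02e-04 and adjusted p = 0.372 with an estimated correlation). Siderophore and iron uptake genes leaned up: 16 rose, 1 fell and 16 did not pass (19 and 1 adjusted over the list alone). Among them were fpvA 3.48 and pfrI 3.27 (median 0.91, camera adjusted p = 1.98e-04 and adjusted p = 0.0295 with an estimated correlation). In all 1035 features rose and 1000 fell. Stationary deletion library 2 has much lower counts than the other two of its group for PP_1400 (98 against 3359 and 3650) and for the phosphate transport gene pstS (115 against 2377 and 2070).

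Over the whole course in the deletion strain, cioA, for a cyanide-insensitive oxidase, rose by 5.09 ± 0.33 (adjusted p = 8.49e-11). RsmZ rose by 4.76 ± 0.51 (adjusted p = 1.33e-07), or 3.96 without deletion stationary 2. The transporter genes PP_1016 and PP_1018 fell, at -7.40 ± 0.39 and -7.05 ± 0.30, grpE at -4.40 ± 0.34 and eda at -4.22 ± 0.247 (n = 3). Ribosomal protein genes leaned down: 0 rose, 50 fell and 4 did not pass (0 and 52 adjusted over the list alone). Among them were rplQ -3.18 and rpmE -3.61 (median -1.63, camera adjusted p = 8.53e-15 and adjusted p = 0.164 with an estimated correlation). For terminal oxidases 10 rose, 3 fell and 1 did not pass (10 and 3 adjusted over the list alone). Among them were ccoO-1 3.05 and ccoN-2 1.80 (median 1.84, camera adjusted p = 0.00136 and adjusted p = 0.169 with an estimated correlation). In all 1205 features rose and 1327 fell.

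Tested as a difference, the effect of the deletion at transition minus that in exponential phase passed for 1707 features, 973 upward and 734 downward, where the authors' scaling gives 794 and 914 and upper-quartile scaling 811 and 905. The sugar uptake genes PP_1017, PP_1016, PP_1018 and oprB-1, higher in exponential and lower at transition phase, differ by -9.70 ± 0.44, -9.51 ± 0.49, -9.10 ± 0.37 and -7.72 ± 0.41. In the other direction aspA differs by 5.34 ± 0.38 (adjusted p = 9.25e-10), PP_3332 by 5.31 ± 0.43 (adjusted p = 7.79e-09) and PP_0496 by 4.40 ± 0.37 (adjusted p = 1.54e-08). Of ribosomal protein genes, with a negative median first and a positive one later, 47 differed upward, 0 downward and 7 did not pass (49 and 0 adjusted over the list alone). Among them were rpmH 3.50 and rpsU 3.36 (median 1.81, camera adjusted p = 2.16e-16 and adjusted p = 0.102 with an estimated correlation). For ATP synthase 9 differed upward, 0 downward and 0 did not pass (9 and 0 adjusted over the list alone). Among them were atpC 3.06 and atpA 2.49 (median 2.40, camera adjusted p = 2.88e-07 and adjusted p = 0.0369 with an estimated correlation), and for translation factors 11 differed upward, 0 downward and 2 did not pass (11 and 0 adjusted over the list alone, median 1.72, camera adjusted p = 8.66e-05 and adjusted p = 0.0369 with an estimated correlation). Of glucose and Entner-Doudoroff genes 2 differed upward, 11 downward and 14 did not pass (2 and 11 adjusted over the list alone). Among them were zwf-1 -3.32 and ptxS -3.14 (median -0.40, camera adjusted p = 6.42e-04 and adjusted p = 0.102 with an estimated correlation). The median of all features was -0.03 against -0.21 with the authors' scaling.

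Between transition and stationary phase the effect of the deletion differed for 1271 features, 621 upward and 650 downward. The betaine and sarcosine genes PP_0308, glyA-1 and soxB, low in the deletion strain at transition phase, differ by 7.26 ± 0.50 (adjusted p = 7.04e-10), 7.05 ± 0.47 (adjusted p = 4.83e-10) and 6.60 ± 0.59 (adjusted p = 4.52e-08). The reverse holds for aspA at -5.98 ± 0.39 (adjusted p = 2.68e-10) and PP_1112 at -6.35 ± 0.71 (adjusted p = 2.93e-06). PP_4619 differs by -4.79 ± 0.60 (adjusted p = 6.67e-06), with a strain effect of -0.07 at transition and -4.86 in stationary phase. Of glucose and Entner-Doudoroff genes 13 differed upward, 2 downward and 12 did not pass (14 and 2 adjusted over the list alone). Among them were zwf-1 3.25 and oprB-1 3.51 (median 1.40, camera adjusted p = 5.56e-04 and adjusted p = 0.368 with an estimated correlation). For chaperones and heat shock 1 differed upward, 12 downward and 13 did not pass (1 and 12 adjusted over the list alone). Among them were lon-1 -2.66 and grpE -2.62 (median -0.64, camera adjusted p = 0.0209 and adjusted p = 0.813 with an estimated correlation).

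Between exponential and stationary phase the effect differed for 1338 features, 793 upward and 545 downward. PP_1083, rpmH and PP_0496, lower in the deletion strain in exponential phase, differ by 4.28 ± 0.42 (adjusted p = 3.15e-07), 4.15 ± 0.41 (adjusted p = 3.80e-07) and 3.80 ± 0.39 (adjusted p = 4.84e-07). Downward differences were PP_4619 at -5.97 ± 0.66 (adjusted p = 2.83e-06), PP_4578 at -5.72 ± 0.38 (adjusted p = 1.30e-09) and rbsC at -5.56 ± 0.31 (adjusted p = 8.04e-11). For ribosomal proteins 43 differed upward, 0 downward and 11 did not pass (50 and 0 adjusted over the list alone). Among them were rplI 2.70 and rpsP 2.84 (median 1.72, camera adjusted p = 8.24e-20 and adjusted p = 0.0688 with an estimated correlation). In the catabolism of aromatic compounds and amino acids 1 differed upward, 12 downward and 41 did not pass (1 and 12 adjusted over the list alone). Among them were lpdV -3.09, hmgA -4.30 and bkdB -2.59 (median -0.95, camera adjusted p = 3.85e-05 and adjusted p = 0.0433 with an estimated correlation). The median of all features was 0.00 against -0.16 with upper-quartile scaling.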

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

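All tests of the 3 patterns below were chosen after the results were seen, while the splits of the libraries and the tests of differences between phases were planned. The results here were picked out because the effect of the deletion differs between growth phases. That difference passed for 1707 features between exponential and transition phase, 1271 between transition and stationary phase and 1338 between exponential and stationary phase, and for 13, 4 and 10 of 31 gene lists with the preset correlation, of which 2, 0 and 2 kept their call with an estimated correlation.

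For transition minus exponential phase, the largest upward log2 differences among named genes were aspA 5.34 ± 0.38, PP_3332 5.31 ± 0.43, PP_0496 4.40 ± 0.37, PP_4966 3.98 ± 0.56 and lsfA 3.82 ± 0.86, and the largest downward ones PP_1017 -9.70 ± 0.44, PP_1016 -9.51 ± 0.49, PP_1018 -9.10 ± 0.37, PP_4578 -8.70 ± 0.39 and oprB-1 -7.72 ± 0.41.

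For stationary minus transition phase they were PP_0308 7.26 ± 0.50, glyA-1 7.05 ± 0.47, PP_3379 7.00 ± 0.92, PP_3533 6.61 ± 1.05 and soxB 6.60 ± 0.59 upward and PP_1112 -6.35 ± 0.71, aspA -5.98 ± 0.39, ssuE -4.91 ± 0.79, PP_4619 -4.79 ± 0.60 and PP_1110 -4.71 ± 0.76 downward. With 1 library left out, PP_3379 was 6.30 without deletion transition 1 and 8.28 without deletion transition 2, PP_3533 was 5.02 without deletion stationary 2 and ssuE was -5.86 without deletion stationary 2.

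For stationary minus exponential phase they were PP_0862 5.11 ± 0.42, PP_1083 4.28 ± 0.42, rpmH 4.15 ± 0.41, PP_0496 3.80 ± 0.39 and efp 3.71 ± 0.83 upward and PP_4619 -5.97 ± 0.66, PP_4578 -5.72 ± 0.38, rbsC -5.56 ± 0.31, PP_1018 -4.82 ± 0.42 and PP_2877 -4.71 ± 0.40 downward. With 1 library left out, PP_0862 was 5.70 without deletion exponential 2 and efp was 2.08 without wild-type exponential 3.

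Strain labels were exchanged within phases in 100 splits for each difference. Such an exchange mostly breaks up the strain effect itself, so these splits do not test whether that effect is equal between phases. Between exponential and transition phase 1 split, the real one, gave as many features as the real 1707, and the highest other gave 1010. Between exponential and stationary phase it was again 1, with 1338 against 746. Between transition and stationary phase 3 of 100 reached the real 1271, the highest other with 1420, and the other splits that did exchanged all strain labels of 1 phase and some of the other, which mostly adds the strain effects up in place of taking their difference. For each of the 9 comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. In each of them only 1 split, the real one, reached the real count, and the highest other counts were 1, 0, 0, 0, 0, 0, 0, 35 and 2 features.

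The first pattern is the near absence of counts from PP_3849 to PP_3920 in the deletion strain. The 20 features beside the region had 44532 counts against 47292 in wild type, most of them from PP_3921. Without PP_3921 the other 19 had, after scaling by library size, 51.5% of wild type in sum and 28.9% in the lowest deletion library, far above the region itself, which argues against a loss of depth in this part of the genome. No deletion library had more than 0.454% of the wild-type mean of its phase, which is what a genome without this region would give. With 65 features at 0 counts, a region that is present but silent without Hfq could look the same, so differences in this region may belong to the strain and not to Hfq. If the region is missing, the strains differ in more than hfq, and changes elsewhere in the genome cannot be assigned to Hfq alone.

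The second pattern is that the deletion strain at transition phase lies toward exponential phase. Its strain effect had the opposite sign to the wild-type change from exponential to stationary phase in 1056 of 1437 features called in both (73.5%). With another scaling 74.6% was the lowest share, so the pattern does not hang on the choice among the scalings tried. An error shared by all of them was not tested. The opposite sign is not a trait of transition phase alone, since the strain effect in stationary phase was opposite to the wild-type change from exponential to transition phase in 983 of 1324 features (74.2%, correlation -0.293), while in exponential phase it was opposite to the change from transition to stationary phase in 262 of 656 (39.9%). Among the most abundant features the spread of changes from exponential to transition phase was 0.597 of that in wild type, and among the least abundant 0.701. The narrowing is thus not limited to rare features, where low depth weighs most, which argues against low depth as its cause. At transition phase the correlation across all features was -0.224, which is weak, so a culture sampled at an earlier stage of growth could give part of this pattern but is not told apart from an effect of Hfq.

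The last pattern is stationary deletion library 2, which lies apart from the other two. Its hfq count of 10 excludes an exchange with wild type. Its first principal component of 42.0 lies beyond the other two (22.8 and 25.7, transition mean -2.16), and component 3 of 2.11 just beyond them (2.30 and 3.48, transition mean 35.6). Components 2 (-33.5) and 4 (3.36) lie between them and the transition means of -2.55 and -27.5, so a sample taken earlier is neither shown nor excluded. On components 1 to 4 the library also lies between the other libraries of its group and those of stationary wild type. The latter lie at 54.0 to 56.1, -11.6 to -10.9, -30.1 to -28.1 and -13.7 to -10.1. Among abundant features 335 were over 2-fold from the mean of the group against at most 117 in any library outside the group, so low depth is excluded. Its phosphate transport genes had a median log2 deviation of -2.18, and a culture with more phosphate left is a candidate explanation that the counts cannot settle.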

How the results depend on the processing

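The 12 counts of changed features were recomputed with a test against a 2-fold change, an adjusted p below 0.01, DESeq2 size factors, upper-quartile scaling, no low-count filter, protein-coding features only, only the groups compared, the DESeq2 test, a replicate block and without each library, and also with the authors' scaling and without the PP_3849 to PP_3920 region, which were chosen after seeing the data. In 204 of these cases the count stayed within 1.5 times the reported one, and in 18 it did not, all of them under the first pair of alternatives. The loss of hfq stayed the same in all 51 cases. No called gene taken by the naming rule reversed under any setting. With the DESeq2 test 1557 of these calls, counted per gene and comparison, stayed and 2 were lost. Leaving out single libraries, counted per gene, comparison and library left out, kept 10905 and lost 501. A pseudocount on normalized values was not varied, since counts were used.

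Asking for a change above 2-fold (glmTreat) left 214, 581 and 287 features for the strains in exponential, transition and stationary phase. For transition against exponential, stationary against transition and stationary against exponential phase it left 1692, 769 and 1916 in wild type, 414, 596 and 1019 in the deletion strain and 611, 432 and 335 for the differences. These counts fall by construction, since the test asks for more. An adjusted p below 0.01 left 699 and 1202 for the strains in exponential and stationary phase, 1198 from exponential to transition phase in the deletion strain, 1099, 772 and 795 for the differences, and, for features with the same direction, 169, 423 and 164, again by construction.

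Without 1 library the counts ranged from 872 to 1201, 1681 to 1964 and 1428 to 2344 for the strains, where the highest in stationary phase came without deletion library 2. With the replicate numbers, which both strains share, as a block, the counts were 1298, 2084 and 1906 for the strains. With the numbers of the cultures within a strain as a block, they were 3196, 2433 and 3369 for the phases in wild type. In the deletion strain they were 1896, 2043 and 2533, and for the differences 1743, 1315 and 1355. All of these lay within 1.5 times the reported counts. For the deletion strain from exponential to transition phase, where the libraries go in pairs, no call of a named gene changed, and antisense RNAs passed as a list with the block (camera adjusted p = 0.0466) and not without it (adjusted p = 0.0623). In the other comparisons their own block added 2 list calls, and no list lost its call. These were NADH dehydrogenase between the strains at transition phase (0.0452 with it, 0.0514 without) and tRNA-overlapping regions from transition to stationary phase in the deletion strain (0.0384 and 0.0563).

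The calls of gene lists change with the test, while scaling, filter and single libraries were not varied for them. With an estimated correlation 1, 0 and 0 lists passed for the strains, 5, 1 and 0 for the phases in wild type, 1, 1 and 0 in the deletion strain and 2, 0 and 2 for the differences. With fry the counts were 16, 21 and 14, then 29, 18 and 25, then 22, 20 and 26, then 15, 9 and 15. Fry asks whether a list changes at all and not whether it changes more than other genes. With an estimated correlation the variance of a list mean grows by construction where its genes vary together.

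As a share of counts outside ribosomal RNA, protein-coding genes were higher in the deletion strain by 0.915, 5.74 and 7.38 percentage points in the 3 phases, while as a share of all counts they differed by -0.605, -0.738 and -0.125, a reversal that follows from the larger ribosomal share. In exponential phase this reversal is not stable, since the difference is -2.84 without deletion exponential 1 and -0.00429 without wild-type exponential 1, and 2.78 without deletion exponential 2, 2.81 without deletion exponential 3, 0.237 without wild-type exponential 2 and 2.51 without wild-type exponential 3. Known small RNAs went to -5.20, -2.01 and -18.4 points in the 3 phases, in the same direction, but in exponential and transition phase the strains overlap on this scale.

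Reversals were limited to features that were not called. In exponential phase hisZ stood at 0.0184 with upper-quartile scaling and RnpB at -0.0082 without the filter. Without 1 library RnpB ranged from -0.26 to 0.31 and rpoS from -0.018 to 0.32 in exponential phase. At transition PP_4897 ranged from -0.049 to 0.23, RsmY from -0.71 to 0.16, RnpB from -0.39 to 0.15 and tmRNA from -0.27 to 0.061. In stationary phase miaA ranged from -0.28 to 0.0015 and 6S RNA from -0.31 to 0.31. For these the cause was not tested. Depth limits the rarest features, since most counts fall in ribosomal RNA and 1 library held 372290 counts in protein-coding genes.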

Other observations

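Q-values deposited by the authors compare single libraries. Below 0.05, a pair of a deletion and a wild-type library has a median of 88, 97 and 86 features in exponential, transition and stationary phase (9 pairs each, ranges 60 to 108, 66 to 112 and 52 to 107). For pairs of replicates of 1 group the medians are 186, 174 and 134 (6 pairs each, ranges 120 to 227, 155 to 206 and 112 to 355), higher than between the strains. These q-values entered none of the results above.

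Among features with at least 100 wild-type counts, copies of the maturase left out, those from PP_3849 to PP_3914 form a run of 33 that each had under 1% of wild type in the deletion strain after scaling by library size. The next longest such run holds 1 feature.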
